A study of Homo sapiens with 47 samples.

How the data were processed

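The series measured the transcriptomes of 47 single HEK293 cells. HEK293 is an established human embryonic kidney line transformed with adenovirus DNA. Per the labels' protocols, cells were lysed in a Fluidigm C1 microfluidic circuit with 96 chambers, and ERCC Spike-In Mix 1, a set of synthetic polyadenylated RNAs of known concentration, was added to the lysis mix at 20000 molecules per cell. Poly(A) RNA was primed with oligo-dT and copied with template switching, so that each cDNA end carried a random tag, the unique molecular identifier (UMI), at the 5' end of the transcript. Amplification took 18 PCR cycles, the barcoded cDNA of all cells was pooled, fragmented with a transposase, and 5' fragments were kept for Ion Torrent sequencing. The tag design allows 20736 different tags. The labels name 1 cell line, 1 run and no treatment, so no groups were compared. Cells are named here by the number in their labels.

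The deposited table holds whole-number UMI counts per gene and cell, not normalized. The submitters' processing notes list cutadapt 1.2.1, STAR 2.4.0a and the genome builds hg19 and GRCh37. The annotation, the tool that collapsed UMIs, the correction of errors in tags, the use of strand, the treatment of reads that map to several places and the filter on cells were not given in the sources used here. Each of the 47 columns matched the label of 1 cell, and 0 columns were left over. The column names carry an additional word that no label explains. A repeated header line, whose numbers sum to 1859 or 0.0602% of all values, names no gene and was left out. The rest were 18651 gene rows, 832 of them without a UMI, and 78 spike-in rows, 77 of them with UMIs. Spike-in rows were kept out of library totals, and all shares are shares of the endogenous UMIs of a cell. The reference annotation at hand is of another genome build than the table, so no coordinates are given.

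Summed over cells there were 2919198 endogenous and 166728 spike-in UMIs. A cell had 29325 to 138647 endogenous UMIs. UMIs limit counting of PCR copies, but the intervals given (95%, exact binomial for shares and exact Poisson for spike-in recovery) cover counting error only. A count of 0 in the summed UMIs allows a share of up to 0.000103%, which is 3 counts of the total. Spike-in recovery is the number of spike-in UMIs divided by the molecules added. An estimate of mRNA molecules per cell is the endogenous UMIs divided by that recovery.

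The spread of each gene over cells was measured by the index of dispersion, the chi-square statistic of its counts against shares proportional to each cell's endogenous UMIs, divided by its degrees of freedom. An index of 1 is the value under counting error alone. The 9088 genes with at least 20 UMIs over all cells were tested. Each index was set against 100000 random draws, one-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, under a multinomial null for counting error, and under a gamma-Poisson null with a single dispersion estimated from the 52 spike-ins with at least 20 UMIs, called spike-in noise below. A further null was added after the spike-ins had been seen: a Dirichlet-multinomial null whose index follows a log-log line fitted to the spike-in index against abundance, called noise that follows abundance. The single dispersion was 0.0171. The fitted line gave an index of 2.28 at a mean of 1 UMI per cell and 1.85 at 100 UMIs per cell.

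Gene lists and markers were fixed before the data were examined: 17 lists of gene groups and 6 lists of cell type markers. The lists were G1/S genes, G2/M genes, replication-dependent histones, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, nuclear oxidative phosphorylation, glycolysis, translation factors, chaperones, immediate-early genes, unfolded protein and integrated stress response, p53 targets, cholesterol synthesis, proteasome, cytoskeleton, RNA splicing and nuclear long non-coding RNAs. The markers were of neuronal, kidney epithelium, adrenal, fibroblast, blood and immune, and pluripotent stem cells. Members without a row are not analysed here. Co-variation within a list is the mean pairwise Spearman correlation over cells of log2(1 + UMIs scaled to the median total), for genes with at least 20 UMIs. It was compared, one-sided, with 10000 random lists of like size, each gene drawn from the 50 nearest genes by mean expression, with adjustment over the 17 lists. For the ribosomal protein genes, which are among the most abundant genes of the table, the random genes were on average less abundant. For 8 pairs of measures, Pearson's r and Spearman's rho over cells were computed with two-sided permutation tests of 100000 resamples, adjusted over the 8.

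Named genes were chosen by a rule fixed before the data were examined: the 20 genes with the most UMIs, the 20 genes with the largest squared coefficient of variation beyond counting error and spike-in noise among genes past the spike-in noise test with a mean of at least 1 UMI per cell, the 4 most abundant members of each list and up to 3 with the largest excess spread among those past that test, up to 3 markers of each cell type with the most UMIs, and the 3 most abundant spike-ins. Other genes are said to have been chosen after their values were seen. A gene that this rule names is not reported here. No clustering or doublet calling was done, and doublets were not assessed. Cells of a single culture are not replicates of a condition: every SD is a spread between cells, and every p-value describes these cells only. The numbers in the labels of the cells were checked as a possible batch, split at 48. No relation of these numbers to endogenous UMIs, spike-in UMIs, ribosomal protein share or mitochondrial mRNA share passed the threshold (permutation tests adjusted over these 4 measures, adjusted p = 0.437 for Pearson's r and 0.281 for Spearman's rho of each).

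The counts of any 2 cells were compared by chi-square over the 953 genes with a mean of at least 10 UMIs per cell. The lowest chi-square per degree of freedom over the 1081 pairs was 2.21, so no library was counted more than once. The tests were checked on simulated counts for the 9088 genes, each test under its own noise model with 10000 draws, with genes given a known squared coefficient of variation. Of 100 genes with a value of 1, the counting error test called 68.0%, the spike-in noise test 62.0% and the test against noise that follows abundance 25.0%. For 100 genes with a value of 0.25 the tests called 33.0%, 31.0% and 13.0%. With a mean of at least 10 UMIs per cell they called 100%, 100% and 92.9% of 14 genes with a value of 0.25. Of 8888 unchanged genes they called 0.0338%, 0.0563% and 0.0563%. The co-variation test called 20 of 20 simulated lists that shared a factor and 0 of 100 that did not. Each list had 20 genes drawn among the 9088, with fewer random lists than in the test of the real counts. These counts held counting error only, and the shared factor had an SD of 0.5 in natural log. They therefore do not show how the test performs for weaker co-variation or with the spread of the real counts.

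Alternatives were other scalings (DESeq2 1.42.0 size factors over genes detected in every cell and edgeR 4.0.16 TMM factors, used only to scale), minimum totals of 5 and 100 UMIs, thinning of each cell to 29325 endogenous UMIs, detection with at least 2 UMIs, a correction for chance reuse of tags, other denominators of shares, Pearson correlation, log2 of both measures and each cell left out in turn. Alternatives used 10000 draws, except the minimum totals, which used the main draws. Leaving out cells with fewer than a set share of the median (19896 endogenous or 1183 spike-in UMIs) removed 0 cells. Leaving out cell 52 and splitting cells by label number were added after the data had been seen. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3.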

Results

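The data are UMI counts of 47 single HEK293 cells of 1 run, with ERCC spike-ins in every cell. The labels give the aim as profiling single HEK293 cells with UMIs, and name no groups. Each cell is therefore described against the spread over all 47. A cell had a median of 59689 endogenous UMIs (SD 22755, n = 47), from 29325 in cell 23 to 138647 in cell 43. Spike-in UMIs ranged less, from 2573 in cell 15 to 4717 in cell 9, with a median of 3550. The median number of genes with a UMI was 6679 per cell, from 4202 in cell 23 to 8947 in cell 43. It was 4547 when at least 2 UMIs were asked for, and 5180 after thinning each cell to 29325 UMIs. In all 17819 genes had a UMI and 1033 had one in every cell.

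Spike-in recovery was 17.7% of the molecules added (exact Poisson interval 17.7% to 17.8%, counting error only), with a range over cells of 12.9% to 23.6%. Dividing by it gave a median of 351477 estimated mRNA molecules per cell, from 179769 in cell 52 to 595691 in cell 43. This estimate takes endogenous mRNA to be counted with the efficiency of the spike-ins. Cells with more spike-in UMIs also had more endogenous UMIs (Pearson's r = 0.723, Spearman's rho = 0.721, both permutation p = 1e-05, the smallest possible, and adjusted p = 4e-05 over 8 relations). Without the 2 cells farthest from the median, 43 and 62, r was 0.703. Cells with more endogenous UMIs had more genes detected after thinning (r = 0.637, rho = 0.620, permutation p = 1e-05, adjusted p = 4e-05), and r was 0.648 without the same 2 cells. In the 17 cells with label numbers above 48 both relations had the same direction but missed the threshold (r = 0.513 and 0.545, adjusted permutation p = 0.0686).

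**Figure D1:**
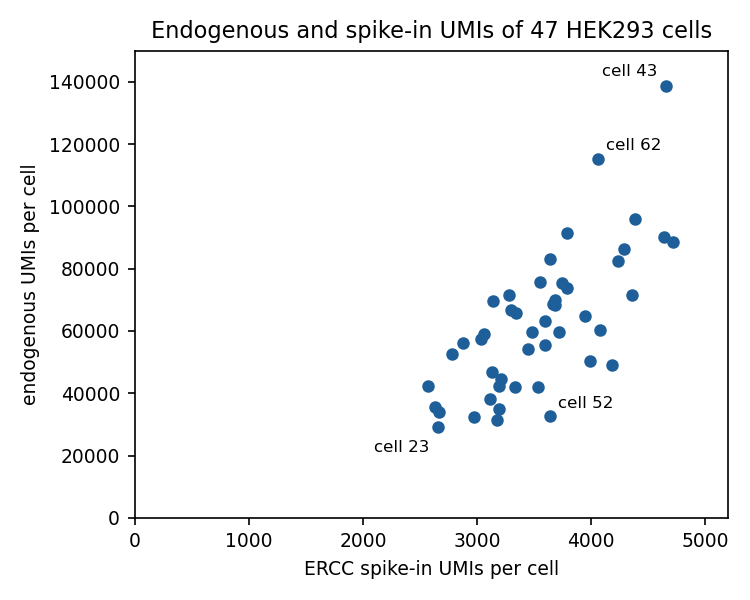
Endogenous UMIs against ERCC spike-in UMIs, each point 1 of 47 cells. Cell 43 has the most endogenous UMIs, 138647, and cell 23 the fewest, 29325.

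Mitochondrial ribosomal RNAs and cytosolic ribosomal protein mRNAs led the table. The most abundant gene was MT-RNR2, the large mitochondrial ribosomal RNA, with 732 ± 228 UMIs per cell (SD, n = 47, not scaled for depth), followed by MT-RNR1, the small one, with 508 ± 241. RPLP1, RPL31, RPL35A and RPS27, proteins of the cytosolic ribosome, had 460 ± 149, 391 ± 120, 379 ± 116 and 378 ± 128. The histone H4 gene HIST1H4C ranked 9 with 353 ± 258, and the ATP synthase subunit gene MT-ATP8 ranked 15 with 298 ± 88.8. The other members of the 20 most abundant genes were RPL37A, RPL11, RPL39, RPS19, RPL36, RPL24, RPL32, RPL41, RPLP2, RPS13, RPL23A and RPS18. Ribosomal protein and histone H4 genes have near-identical copies or pseudogenes, and mitochondrial genes have nuclear copies, so their counts are uncertain to the extent that reads were shared.

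The spike-ins gave the technical spread. ERCC-00074, the most abundant, had 801 ± 85.7 UMIs per cell and an index of 3.76 (adjusted p = 3.47e-05). ERCC-00002 had an index of 1.2 (adjusted p = 0.172) and ERCC-00130 an index of 0.757 (adjusted p = 0.886). In all 49 of 52 spike-ins exceeded counting error in the Monte Carlo test, with a median index of 2.11 and a range of 0.757 to 3.97. The log-log slope of the index on abundance was -0.0456. The median index was 2.14 for 31 spike-ins with 20 to 500 UMIs and 1.59 for 8 with at least 7000.

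Most genes varied between cells by more than counting error, and the number beyond technical spread depended on how that spread was described. Of 9088 genes, 7935 (87.3%) exceeded counting error and 7537 (82.9%) exceeded spike-in noise with a single dispersion. That dispersion, 0.0171, was below those of most rare spike-ins, whose median index was 2.14 at 20 to 500 UMIs. For genes with few UMIs, passing it here and in the lists below therefore does not show spread beyond technical noise. Against noise that follows abundance, the null added later, 290 genes (3.19%) passed, with 943 at an unadjusted p under 0.05. The median index of all genes was 2.00, near that of the spike-ins. The null that follows abundance takes its fitted line as exact. Single spike-ins had an index of up to 3.97, and ERCC-00074, the most abundant, had 3.76. Here and in the lists below, passing with an index no higher than these does not show spread beyond technical noise. Past both spike-in nulls were 236 genes, of which 21 were mitochondrially encoded and 154 were in none of the 17 lists of gene groups (3 of them neuronal markers). The self-test given with the processing called 25.0% of 100 simulated genes with a squared coefficient of variation of 1 against noise that follows abundance, so a gene with few UMIs that did not pass is not shown to be even.

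**Figure D2:**
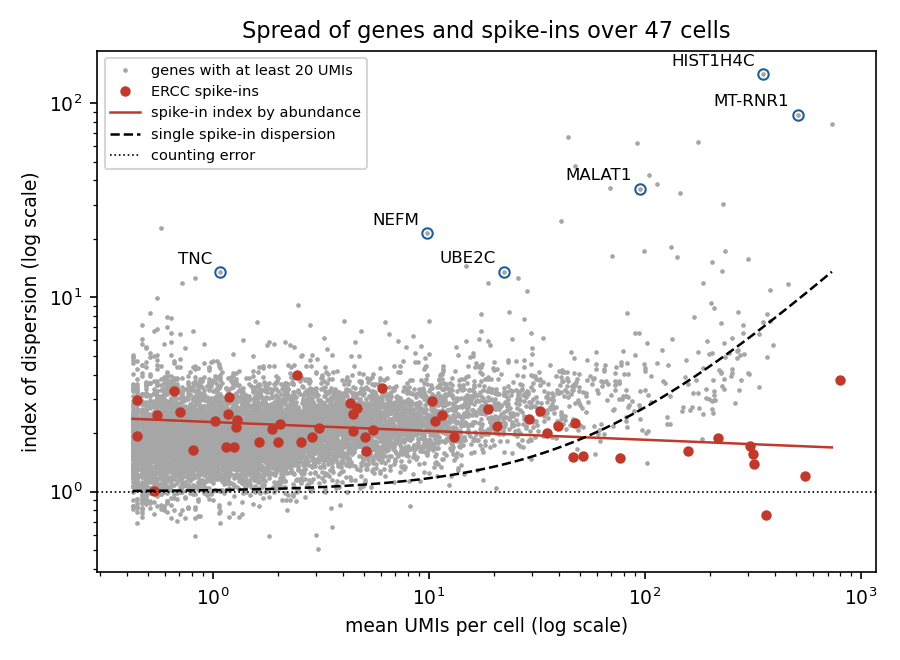
Index of dispersion against mean UMIs per cell, both on log scales, for 9088 genes (grey) and 52 ERCC spike-ins (red), with lines for counting error, the single spike-in dispersion and the spike-in index by abundance. HIST1H4C has the highest index, 141, while spike-ins lie between 0.757 and 3.97.

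Among genes with a mean of at least 1 UMI per cell, those with the largest excess spread were detected in a part of the cells. TNC, which encodes the matrix protein tenascin-C, had 51 UMIs in 7 cells, 29 of them in cell 62 and 16 in cell 27. LGALS3, which encodes galectin-3, had 75 UMIs in 18 cells, 19 of them in cell 3. The indices of TNC, LGALS3, RP11-120I21.2, PAAF1, LRRC8A and NFKBIB were 13.5, 7.49, 9.16, 5.92, 5.66 and 6.02, and these genes also passed against noise that follows abundance (adjusted p from 0.000783 to 0.0401). Without its highest cell after scaling, the index was 12.7 for TNC (cell 27), 3.64 for LGALS3 (cell 3), 6.09 for RP11-120I21.2 (cell 57), 3.10 for PAAF1 (cell 74), 2.21 for LRRC8A (cell 80) and 1.86 for NFKBIB (cell 52). The remaining genes named by this rule, FGFR4, JOSD2, C10orf35, BAIAP2, PRR24, VAMP4, TMEM131, AHCTF1, CYTH3, SCLY, KIAA0586, TCF4, ALG2 and CAPN10, had indices from 3.77 to 5.09 and did not pass that test (adjusted p from 0.104 to 0.418). Without their highest cells their indices were 1.61 to 4.05.

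In the lists below, each count of genes past spike-in noise and past noise that follows abundance is over all genes tested, and is followed by the count adjusted over the list alone. Shares are of the summed endogenous UMIs, with the range over the 47 cells. Co-variation is the mean pairwise rho, with a one-sided permutation-type p from random lists, adjusted over 17 lists. The smallest p possible is 1e-04, adjusted 0.000283. Excess spread of a list member is relative to the single dispersion, and for a given index is larger at a lower mean. Of the members named for it, HIST1H1D, RPL8, RPL3, MT-ND4, MT-ND5, MT-CO1, EIF4A2, HSPA1B, FDXR and NEAT1 also passed against noise that follows abundance, and the others did not (adjusted p from 0.0677 to 1).

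Cell cycle genes varied together within each phase. G2/M genes took 0.568% of UMIs, from 0.304% in cell 23 to 1.03% in cell 53. UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, had 22.3 ± 22.6 UMIs per cell (index 13.6), and CKS2, a CDK-binding subunit, had 29.7 ± 18.3 (index 6.58). HN1 and TUBB4B were the other abundant members, with indices of 4.78 and 3.01, and CENPA, CDC25C and GAS2L3 had the largest excess spread at low means. Of 54 genes, 51 exceeded spike-in noise and 8 noise that follows abundance (51 and 11 adjusted over the list alone). Co-variation was 0.147 (adjusted p = 0.000283, random median 0.0181), and 0.0927 after thinning. G1/S genes took 0.443%, from 0.246% in cell 10 to 0.724% in cell 3. PCNA, the DNA polymerase clamp, had 15.1 ± 10.2 UMIs (index 4.42), and RPA2, a subunit of the single-strand DNA binding complex, had 41.3 ± 21.1 (index 4.25). GMNN and NASP had indices of 2.65 and 3.25, and CCNE2 and BRIP1 were among those with the largest excess spread. Of 43 genes, 40 and 2 passed (40 and 2 adjusted over the list alone), with co-variation of 0.129 (adjusted p = 0.000283, random median 0.0165), and 0.0751 after thinning.

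The G1/S and G2/M shares had r = -0.271 (permutation p = 0.0643, adjusted p = 0.0735) and rho = -0.209 (p = 0.157, adjusted p = 0.202), so the relation missed the threshold. It was -0.353 without cells 3 and 10, and the adjusted p of r was below the threshold without cell 10 (r = -0.325) or cell 23 (r = -0.320). The G2/M share and the ratio of endogenous to spike-in UMIs had r = 0.277 (p = 0.0584, adjusted p = 0.0735) and rho = 0.329 (p = 0.0240, adjusted p = 0.0384), with r = 0.282 without cells 53 and 39. The threshold was passed by r without cell 43 (0.355) or cell 53 (0.316) and on a log2 scale (0.324). In cells numbered up to 48 rho was 0.571 and above 48 it was -0.169, a difference that missed the threshold (permutation p = 0.0116, adjusted p = 0.0928). The G1/S share and that ratio had r = 0.177 (p = 0.235, adjusted p = 0.235) and rho = 0.143 (p = 0.338, adjusted p = 0.338), with r = 0.173 without cells 3 and 10.

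**Figure D3:**
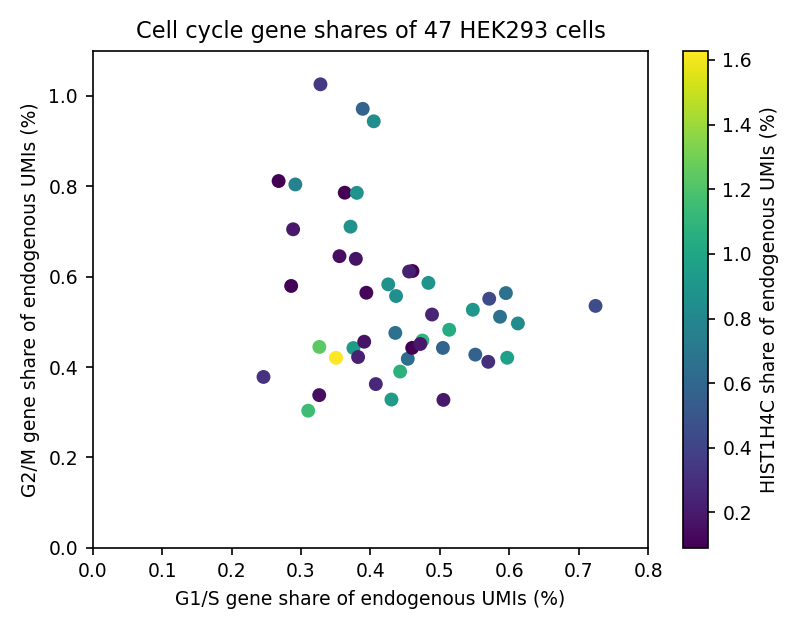
Share of endogenous UMIs of G2/M genes against that of G1/S genes (both in percent), each point 1 of 47 cells, coloured by the share of HIST1H4C (percent). The G2/M share ranges from 0.304% to 1.03% and the G1/S share from 0.246% to 0.724%.

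Replication-dependent histones, which package newly copied DNA, ranged 17.7-fold between cells. They took 0.604% of UMIs, from 0.0975% in cell 16 to 1.72% in cell 8. HIST1H4C held 16578 of their 17618 UMIs and had the highest index of all genes, 141 (adjusted p = 5.88e-05 against spike-in noise and 0.000783 against noise that follows abundance). The linker histone gene HIST1H1D had an index of 5.66 (adjusted p = 0.0225 against noise that follows abundance). HIST1H2BK, HIST1H1E and HIST1H1C had indices of 1.98, 3.77 and 3.57, and HIST1H2BJ and HIST1H2BC had large excess spread at 21 and 20 UMIs. All 11 tested genes exceeded spike-in noise and 2 noise that follows abundance (11 and 5 adjusted over the list alone). Co-variation was 0.242 (adjusted p = 0.000283, random median 0.00747). It was 0.140 with a minimum of 5 UMIs per gene, 0.485 with 100 and 0.419 after thinning, past the threshold each time. Many histone mRNAs lack poly(A) tails, and the library was primed with oligo-dT.

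Mitochondrially encoded mRNAs, which encode subunits of the respiratory chain and ATP synthase, had the highest mean pairwise rho of the 17 lists. They took 3.19% of UMIs, from 2.21% in cell 33 to 12.1% in cell 52, with 5.02% the highest of the other 46 cells. MT-ATP8, MT-CO2, MT-CYB and MT-CO3 had 298 ± 88.8, 235 ± 79.6, 229 ± 73 and 205 ± 69.8 UMIs per cell. MT-ND4, MT-ND5 and MT-CO1 had the largest excess spread, with indices of 63.4, 62.1 and 42.5, which were 17.1, 12.6 and 9.97 without cell 52. All 13 genes exceeded spike-in noise and 12 noise that follows abundance (13 and 13 adjusted over the list alone). Co-variation was 0.572 (adjusted p = 0.000283, random median 0.133). That random median was also the highest of the 17 lists, so the values of different lists are not directly comparable. MT-ATP8 overlaps MT-ATP6 and MT-ND4L overlaps MT-ND4, so reads in those parts cannot be assigned to either. The genes of each pair are therefore not independent members of the list, in its ranks or its co-variation.

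Cytosolic ribosomal protein mRNAs took 26.5% of UMIs, from 18.4% in cell 52 to 31.9% in cell 23. Their most abundant members are given above. RPL8, RPL3 and RPS9 had the largest excess spread, with indices of 11.9, 6.59 and 3.22. Of 79 genes, 11 exceeded spike-in noise and 50 noise that follows abundance (6 and 67 adjusted over the list alone). The single dispersion allows abundant genes a wider spread than abundant spike-ins showed. The median index of the 79 genes was 3.62, below the 3.76 of ERCC-00074, so the 50 do not all show spread beyond technical noise. Co-variation was 0.228 (adjusted p = 0.000283, random median 0.0428), with random genes that were less abundant.

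Nuclear genes of oxidative phosphorylation took 3.72% of UMIs, from 2.17% in cell 52 to 4.36% in cell 75. COX7C, ATP5E, ATP5G3 and ATP5G1, subunits of cytochrome oxidase and ATP synthase, had 154 ± 55.9, 106 ± 35.5, 101 ± 46.8 and 100.1 ± 42.6 UMIs per cell. CYC1, COX8A and ATP5A1 had the largest excess spread. Of 43 genes, 26 and 16 passed (26 and 28 adjusted over the list alone), with co-variation of 0.0739 (adjusted p = 0.000283). It was 0.0432 without cell 52, 0.0453 with DESeq2 size factors, 0.163 with TMM scaling and 0.112 with Pearson correlation, past the threshold each time. Glycolysis genes took 1.09%, from 0.738% in cell 55 to 1.49% in cell 23. GAPDH and ENO1 had 193 ± 68.8 and 98.6 ± 37.9 UMIs per cell, LDHB and TPI1 followed, and PFKL, ALDOC and PDK1 had the largest excess spread. Of 20 genes, 15 and 5 passed (14 and 9 adjusted over the list alone), with co-variation of 0.0480 (adjusted p = 0.00548). It was 0.120 with a minimum of 100 UMIs, and 0.0735 with TMM scaling, not past the threshold (adjusted p = 0.177).

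Cell 52 stood apart in composition. Besides the highest mitochondrial mRNA share it had the highest summed share of the mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 (6.38%, others up to 3.68%) and of nuclear long non-coding RNAs (1.15%, others up to 0.943%). It had the lowest ribosomal protein share (18.4%, others from 24.1%), and the lowest shares of nuclear oxidative phosphorylation (2.17%, others from 3.06%), translation factor (1.52%, others from 1.62%), proteasome, cytoskeleton and splicing genes. It had 32709 endogenous UMIs and 1.08 mitochondrial mRNA UMIs per spike-in UMI, against at most 0.797 in the others. Its spike-in recovery was 18.2%. Shares are parts of the same total, so the high mitochondrial shares of cell 52 by themselves lower its other shares. Which of its lowest shares would stay lowest without mitochondrial RNA was not computed.

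Ribosomal protein and mitochondrial mRNA shares were both lower in cells with more endogenous UMIs. For ribosomal proteins r was -0.400 (permutation p = 0.0061, adjusted p = 0.0163) and rho -0.501 (p = 0.00037, adjusted p = 0.00074), with r = -0.568 without cells 52 and 23. In cells numbered above 48, which include cell 52, r was 0.0677 (rho -0.191), and in those up to 48 it was -0.691 (rho -0.718). The difference of the rho values missed the threshold (adjusted permutation p = 0.208). For mitochondrial mRNAs r was -0.397 (p = 0.0181, adjusted p = 0.0302) and rho -0.544 (p = 0.00012, adjusted p = 0.00032), with r = -0.490 without cells 52 and 51. Cells numbered up to 48 gave r = -0.50 and those above 48 gave r = -0.569, the latter with an adjusted permutation p of 0.0686. Between the 2 shares r was -0.399 (p = 0.0189, adjusted p = 0.0302) and rho 0.201 (p = 0.177, adjusted p = 0.202). That relation rested on cell 52: r was 0.146 without it and 0.0958 without cells 52 and 23.

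**Figure D4:**
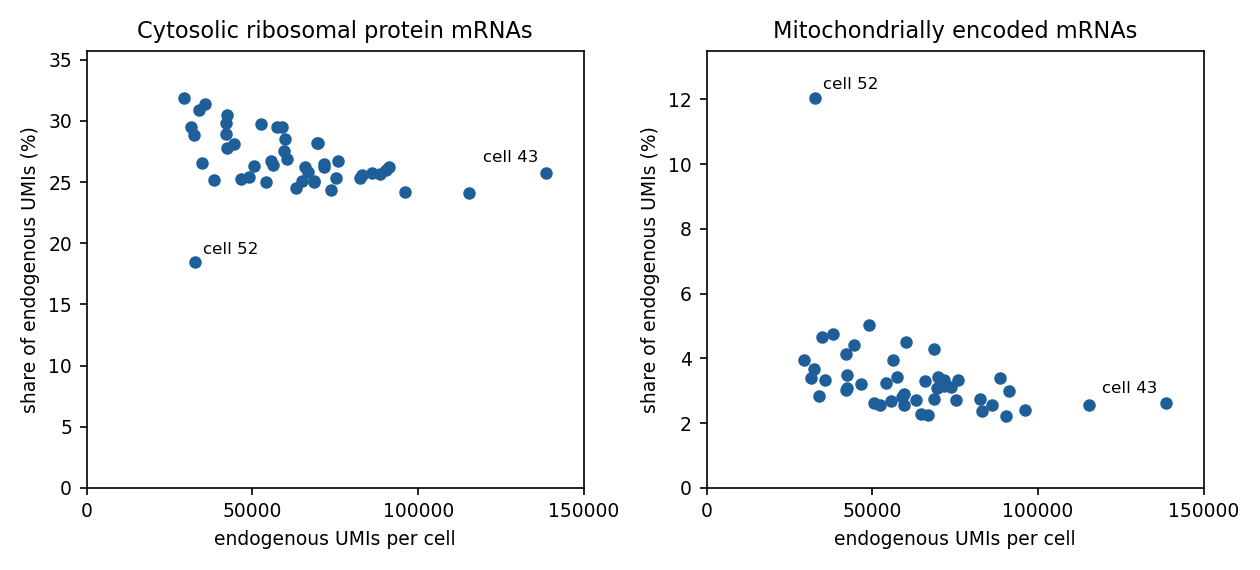
Share of endogenous UMIs (percent) of cytosolic ribosomal protein mRNAs (left) and mitochondrially encoded mRNAs (right) against endogenous UMIs, each point 1 of 47 cells. Cell 52 lies apart, with 18.4% and 12.1%.

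Translation factors took 2.03% of UMIs (1.52% in cell 52 to 2.28%). NPM1, a nucleolar ribosome assembly factor, had 221 ± 93.3 UMIs per cell, followed by GNB2L1, NACA and EEF1A1, while EIF4A2, EIF1AX and EEF1D had the largest excess spread. Of 23 genes, 16 and 8 passed (16 and 12 adjusted over the list alone). Co-variation was 0.0410 (adjusted p = 0.0898), and 0.0389 without cell 52 (adjusted p = 0.0134). Chaperones took 1.56% (1.05% in cell 31 to 1.80%). HSPA1B, a heat-inducible HSP70 gene with a near-identical copy, had 18.8 ± 15.5 UMIs and an index of 11.8, against 5.19 for the more abundant PPIA and 6.58 for HSP90AB1. HSPD1 and HSP90AA1 were also abundant, and HSPH1 and DNAJB1 had large excess spread. Of 31 genes, 27 and 8 passed (28 and 12 adjusted over the list alone). Co-variation was 0.0389 (adjusted p = 0.0180). It was 0.0814 with TMM scaling and 0.0455 with Pearson correlation, neither past the threshold (adjusted p = 0.335 and 0.0871).

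Immediate-early genes took 0.0804% (0.0307% to 0.149%). The transcription factor gene MYC had 10.0 ± 9.73 UMIs (index 5.11, adjusted p = 0.00136 against noise that follows abundance). JUN, SRF and DUSP1 followed, and CYR61, BTG2 and ATF3 had the largest excess spread. Of 16 genes, 15 and 1 passed (15 and 3 adjusted over the list alone), with co-variation of 0.0854 (adjusted p = 0.0017). Genes of the unfolded protein and integrated stress response took 0.181% (0.121% to 0.302%), led by the transcription factor gene ATF4 with 21.1 ± 11.4 UMIs, then SARS, SLC3A2 and PSAT1. ATF5, SLC7A11 and VEGFA had the largest excess spread. Of 24 genes, 23 and 0 passed (23 and 0 adjusted over the list alone, and 4 against noise that follows abundance at an unadjusted p under 0.05), with co-variation of 0.0329 (adjusted p = 0.138), and 0.0346 after thinning (adjusted p = 0.0389). The p53 targets took 0.0345% (0.00341% to 0.0664%), led by the apoptosis gene PMAIP1 with 5.96 ± 5.30 UMIs, then XPC, MDM2 and C12orf5. Of 13 genes, 11 and 1 passed (11 and 2 adjusted over the list alone), with co-variation of 0.0555 (adjusted p = 0.0910). FDXR had an index of 7.93 and 1.32 without cell 3, and CDKN1A and DDB2 had large excess spread.

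Cholesterol synthesis genes took 0.142% (0.0936% to 0.221%), with FDFT1, the squalene synthase gene, at 12.3 ± 6.75 UMIs, then ACAT2, DHCR7 and FDPS. MVK, MVD and STARD4 had the largest excess spread over the single dispersion, with indices of 2.88, 2.38 and 1.54 (adjusted p of 0.835, 0.998 and 1 against noise that follows abundance). Of 22 genes, 20 and 2 passed (20 and 3 adjusted over the list alone), with co-variation of 0.0257 (adjusted p = 0.329). Proteasome genes took 0.864% (0.688% to 1.02%), led by PSMB1 with 48.9 ± 23.8 UMIs, then PSMB3, PSMA7 and PSMB6. PSMD12, PSMC3 and PSMC5 had the largest excess spread. Of 27 genes, 22 and 2 passed (22 and 2 adjusted over the list alone), with co-variation of 0.0261 (adjusted p = 0.209). Cytoskeleton genes took 1.48% (1.19% to 1.88%), with the actin genes ACTG1 and ACTB at 169 ± 64.3 and 133 ± 54.5 UMIs, then TUBA1B and PFN1. KRT18, TMSB4X and MSN had the largest excess spread. Of 29 genes, 25 and 7 passed (25 and 12 adjusted over the list alone), with co-variation of 0.0215 (adjusted p = 0.108). TMM scaling gave 0.0562 for this list, 0.0984 for proteasome, 0.145 for translation factor and 0.0524 for stress response genes, DESeq2 size factors gave 0.0138 for proteasome and 0.0154 for translation factor genes, and thinning gave 0.0140 for proteasome, 0.0124 for cholesterol and 0.00414 for p53 genes, without passing the threshold.

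Splicing genes took 1.55% (1.28% to 1.85%), led by the spliceosome protein gene SNRPD2 with 88.7 ± 37.5 UMIs, then SNRPE, SNRPG and SNRPB. DDX39B, U2AF2 and SRSF1 had the largest excess spread over the single dispersion, with indices of 1.45, 1.93 and 2.57 (adjusted p of 1, 1 and 0.793 against noise that follows abundance). Of 32 genes, 27 and 3 passed (27 and 7 adjusted over the list alone), with co-variation of 0.0519 (adjusted p = 0.00121), and 0.126 with TMM scaling. Nuclear long non-coding RNAs took 0.545% (0.221% in cell 87 to 1.15% in cell 52). MALAT1, a nuclear speckle RNA, had 95.1 ± 63.5 UMIs per cell and an index of 36.3. XIST, the RNA of X inactivation, had 70.4 ± 40.9 and an index of 16.4, and NEAT1, the RNA of paraspeckles, had 7.21 ± 7.49 and an index of 5.99. SNHG5 and SNHG8 were also abundant, and KCNQ1OT1 and TUG1 had large excess spread. Not all members of this list are nuclear RNAs, and location in the cell was not measured. Of 12 genes, 12 and 5 passed (12 and 9 adjusted over the list alone), with co-variation of 0.0593 (adjusted p = 0.0274). It rose to 0.0984 with TMM scaling and fell to 0.0310 after thinning, neither past the threshold (adjusted p = 0.177 and 0.151).

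Only some cell type markers had a row: 6 of 15 neuronal, 6 of 16 kidney, 3 of 9 adrenal, 3 of 10 fibroblast, 4 of 13 blood and immune and 2 of 9 pluripotent stem cell markers. The others are not analysed here, so the lists cannot be ranked. Neuronal markers with a row had 1415 UMIs (0.0485%, exact binomial interval 0.0460% to 0.0511%, counting error only). UCHL1, a neuronal ubiquitin hydrolase, had 817 UMIs in 47 cells, and the neurofilament genes NEFM and NEFL had 462 in 42 cells and 112 in 30. All 3 passed both spike-in nulls (3 and 3 adjusted over the list alone). The index was 21.3 for NEFM, 5.54 for NEFL and 3.72 for UCHL1, the last within the range of the spike-ins. Kidney epithelium markers had 125 UMIs, led by GATA3 with 56, LHX1 with 33 and LRP2 with 26. Of 3 tested, 2 exceeded spike-in noise and 0 noise that follows abundance (2 and 0 adjusted over the list alone). Pluripotent stem cell markers had 118 UMIs, 90 of LIN28B and 28 of DNMT3B, and 2 and 0 of 2 passed (2 and 0 adjusted over the list alone). Neither of these marker lists had a gene at an unadjusted p under 0.05 against noise that follows abundance. Adrenal markers had 3 UMIs, 1 each of CYP11A1, CYP21A2 and NR5A1. Fibroblast markers had 22, of which COL1A1 had 12, 8 of them in cell 67, FN1 had 9 and COL1A2 had 1. Blood and immune markers had 9, of which HBA1 and CD79A had 4 each and CD3D had 1. CD74 had 0 UMIs, which allows a share of up to 0.000103%. No adrenal, fibroblast or blood marker had enough UMIs to be tested.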

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

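Leaving out cell 52, splitting cells by label number and noise that follows abundance were chosen after the data had been seen. Of the values recomputed under an alternative, 575 kept their side of the threshold or moved within the limits set. Of the others, 14 were weaker, 8 stronger, 2 moved and 3 reversed. These values include each of the 8 relations with each of the 47 cells left out. Relations that missed the threshold both times counted as kept even where r changed sign. G2/M share and the ratio of endogenous to spike-in UMIs did so in cells above 48 (r = -0.128, against 0.277 in all cells). Genes past spike-in noise numbered 290 where the noise follows abundance, 236 of them shared with the 7537. With at least 100 UMIs, where fewer genes are tested, 3520 genes exceeded counting error and 3248 spike-in noise. After thinning, 3987 exceeded counting error, with fewer UMIs. Genes detected per cell were 4547 with at least 2 UMIs and 5180 after thinning. On a log2 scale r was 0.324 for G2/M share and the endogenous to spike-in ratio, and -0.296 for ribosomal protein and mitochondrial shares (adjusted permutation p = 0.0390 and 0.0575). The cause was not tested.

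In cells numbered up to 48, which do not include cell 52, r was 0.478 for G2/M share and that ratio. It was 0.396 for ribosomal protein and mitochondrial shares. In the cells above 48, r for G2/M share and that ratio was -0.128. In the 17 cells above 48, fewer than in the whole, r was 0.513 for endogenous and spike-in UMIs, 0.545 for endogenous UMIs and genes detected, -0.687 for ribosomal protein and mitochondrial shares, 0.0677 for ribosomal protein share and endogenous UMIs, and -0.569 for mitochondrial share and endogenous UMIs. Cell 52 is among these 17 cells, and rho there was 0.0956 for ribosomal protein and mitochondrial shares, against r = -0.687. For ribosomal protein share and endogenous UMIs rho was -0.191, so only r changed sign. Over all cells r of that relation was -0.597 without cell 52. The cells above 48 were not tested without cell 52. Leaving out each cell in turn gave ranges of r from 0.695 to 0.751, 0.603 to 0.679, -0.325 to -0.229, 0.241 to 0.355, 0.103 to 0.224, -0.440 to 0.146, -0.597 to -0.358 and -0.485 to -0.383 for endogenous and spike-in UMIs, endogenous UMIs and genes, G1/S and G2/M shares, G2/M share and the ratio, G1/S share and the ratio, ribosomal protein and mitochondrial shares, ribosomal protein share and endogenous UMIs, and mitochondrial share and endogenous UMIs. The value 0.146 is without cell 52. Leaving out shallow cells removed none and gave no separate value, and with at least 100 UMIs the p53 list had too few genes for a value. Depth limits genes with few UMIs most.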

Other observations

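The gene relations in this part, the tests of uneven capture and of equal extra UMIs for the spike-ins, the tests for HIST1H4C, and the tests of the unmatched and the closely matched ribosomal protein genes and of G2/M share were chosen after the result was seen. Among genes past both spike-in nulls that are in no list, named after their values were seen, the mitochondrial transfer RNA genes MT-TS2, MT-TF and MT-TP had indices of 66.8, 47.5 and 36.4, each highest in cell 55 after scaling. Without that cell the index of MT-TS2 was 42.7. Transcription regulator genes were among them too: ID2 had 14.9 ± 18.3 UMIs per cell (SD, n = 47, index 14.5, and 9.09 without cell 38), SOX4 28.3 ± 23.5 (index 10.8, and 6.79 without cell 45) and HES1, a Notch target, 23.5 ± 16.9 (index 8.42). CA2, a carbonic anhydrase gene, had 25.9 ± 25.5 (index 12.6). Other genes had nearly all their spread from 1 cell: the index of SLC28A2 was 22.8 and 1.17 without cell 74, and that of SLC13A4 was 11.9 and 1.54 without cell 39.

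NEFM had 49.8% of its UMIs in 5 cells. Its share went with that of NEFL (r = 0.433, rho = 0.488, permutation p = 0.00773 and 0.00076, adjusted p = 0.0135 and 0.00133 over 7 relations), with r = 0.292 without cells 7 and 57, but not detectably with that of UCHL1 (r = 0.0340, rho = 0.0168, adjusted p = 0.822 and 0.911). UBE2C and TOP2A, both G2/M genes, had r = 0.669 and rho = 0.622 (both permutation p = 2e-05, adjusted p = 7e-05), with r = 0.609 without cells 9 and 39. MALAT1 and XIST had r = 0.606 and rho = 0.524 (permutation p = 4e-05 and 0.00023, adjusted p = 9.33e-05 and 0.000537), with r = 0.386 without cells 52 and 31.

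Of 52 spike-ins, 49 varied beyond counting error, with a median index of 2.14 at 20 to 500 UMIs and 1.59 at 7000 or more. Uneven capture of single spike-in species between cells would raise the index with abundance. The slope of log2(index - 1) on log2(mean) over 51 spike-ins was -0.0283 (95% bootstrap interval -0.170 to 0.157), which argues against it. The index is scaled by the spike-in total of each cell, so the slope does not bear on capture that differs between whole cells. Spike-in recovery ranged from 12.9% to 23.6% over cells. A candidate explanation is that several UMIs were counted per captured molecule, through errors in tags or repeated template switching: 8217 genes with 20 to 500 UMIs had a median index of 1.94 (1.93 to 1.96), above the lower quartile of 1.85 of 31 spike-ins of like totals, as this needs, but below their median of 2.14 (1.92 to 2.51), and true variation between cells also raises it. Whether abundant spike-ins carry as many extra UMIs stays open. For 8 of them the index divided by (1 - share of all spike-in UMIs) had a median of 1.71 (1.42 to 2.01). That interval holds the lower quartile of 1.85. No biological explanation was tested for the spike-ins.

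HIST1H4C had the highest index of dispersion, a measure that grows with abundance, while its squared coefficient of variation beyond technical noise was 0.378, against 2.05 for NEFM. A difference in depth would tie its share to endogenous UMIs, and rho was -0.00347 (95% bootstrap interval -0.283 to 0.285), which argues against depth. As a hypothesis, cells in S phase may hold most histone mRNA: rho with the summed share of HIST1H1E, HIST1H1D, HIST1H3B, HIST1H4E, HIST1H2BN, HIST1H2AG and HIST1H4H, which leaves out H1F0 and histones also made with a poly(A) tail, was 0.829 (0.727 to 0.889, permutation p = 1e-05, the smallest possible), with all 15 other list members 0.846 (0.736 to 0.904) and with the 8 left out 0.601 (0.351 to 0.782). The share of HIST1H4C did not go detectably with that of G1/S genes (r = 0.118, rho = 0.171, adjusted p = 0.503 and 0.290) or G2/M genes (r = -0.152, rho = -0.233, adjusted p = 0.427 and 0.160). Reads shared among histone H4 genes and the capture of histone mRNAs without poly(A) tails were not tested and stay open.

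The ribosomal protein share was lower in cells with more UMIs. Loss of UMIs of abundant genes in deep cells would lower other abundant genes as much: the median rho with endogenous UMIs of 53 other genes exceeded that of the ribosomal protein genes they were matched to by 0.155 (95% bootstrap interval 0.0535 to 0.267), but these had a median mean of 93.8 against 178 UMIs per cell, so the difference decides nothing. For 31 pairs within 1.2-fold (113 against 126 UMIs) the difference was 0.0754 (-0.0941 to 0.171), which leaves such a loss open. The 26 ribosomal protein genes without a match, of higher abundance, had a median rho that differed from that of the matched ones by -0.152 (-0.256 to -0.0106). Such a loss would give this direction. Counting error also pulls rho toward 0 less in more abundant genes, so the difference does not decide. Given the G2/M share the relation was weaker: rho was -0.501 and the partial rho -0.350 (-0.595 to -0.0655, permutation p = 0.0173). G2/M genes took only 0.568% of UMIs, so their share measures the cell cycle with error. A partial rho away from 0 therefore cannot show whether G2/M cells account for none, a part or the whole of it, and this stays open.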
